A study of Mus musculus with 6 samples.

How the data were processed

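Gene expression was measured in R1 cells, a male mouse embryonic stem cell line of a 129X1 x 129S1 cross. The cells were grown on gelatin in medium with fetal bovine serum and LIF, the cytokine that holds mouse embryonic stem cells in self-renewal. They were cultured for 3 days without addition or with 0.74 mM (250 µg/ml) AA2G, ascorbic acid 2-glucoside (called 2-glucose in the labels), a vitamin C derivative that is stable in culture medium and from which α-glucosidases release ascorbate. Each group has 3 samples, which the labels call independent replicates, and each sample was hybridised to 1 array of the type Mouse Gene 2.0 ST from Affymetrix.

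The deposited values are log2 expression values made with RMA (background correction, quantile normalization between arrays and a summary per transcript cluster) in Affymetrix Expression Console, per the submitters' processing notes. The software versions, the annotation release and any filter are not given in the sources used here. On all 6 arrays the values ran from 1.20 to 13.2, and the array medians lay between 5.06 and 5.10. The table of values has 6 columns of samples, all of which were used. It carries no detection calls, so a low value cannot be told from background and is given as measured. Quantile normalization makes the distributions of all arrays alike, so a change in the total amount of RNA per cell is not seen, and summarised log2 values of dim features understate fold changes. An array gives no read depth, and the number of arrays limits the precision.

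The table has 41345 features. The platform annotation gives exactly 1 gene symbol to 23521 of them, several symbols to 1814 and no listed symbol to 16010. Only features with 1 symbol were tested, and these stand for 22180 genes. Symbols were checked against NCBI RefSeq genes of GRCm38.p6 through the Entrez Gene identifier: 23328 features matched, 193 did not, and 0 symbols changed. Because the array's genome build is not given in the sources used here, no coordinates are reported, and the RefSeq table was used only for names, chromosomes and the order of genes.

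AA2G was compared with untreated cells in 1 linear model over the 6 arrays, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided, no covariate). p-values were adjusted by the Benjamini-Hochberg method over the 23521 features, and a gene was called changed at an adjusted p under 0.05. All log2 fold changes are AA2G minus untreated, values per group are means ± SD over 3 arrays, and errors of fold changes are the fitted standard errors (SE). An exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so single genes were tested only in the model that shares its variance estimate across genes. The p-values measure the spread between these 3 cultures a group. The labels name no batch or scan date.

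The model, the alternatives, 29 gene lists and the rule for named genes were fixed before the data were examined. The lists cover germline genes, pluripotency, 6 other cell types that a stem cell culture could hold, enzymes that use ascorbate as a cofactor, and metabolic and stress pathways. Of their 615 entries, 62 had no feature with a single symbol. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 feature per gene, the brightest over the 6 arrays, and with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list moved against the other genes. Fry asks whether its genes moved, on balance, one way. Camera was also run with the correlation estimated from the data, a setting that also refers its statistic to the model's 4 residual degrees of freedom. Beside the calls over all features, each list has a count adjusted over the list alone.

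Named genes are the 10 largest rises and 10 largest falls among called features whose AA2G and untreated arrays do not overlap, up to 4 members of each list with the smallest unadjusted p, and 12 genes fixed by name. Small RNA genes, predicted genes, Rik clones and olfactory and vomeronasal receptors were left out of the first part, which set aside 34 called features. One of the 12 fixed genes, Sycp3, lies on a feature with several symbols and was not tested. Where a named gene has a second feature, its value is given too. Genes named outside this rule are marked as chosen after their values were seen.

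Alternatives were quantile normalization applied again, arrays shifted to 1 median, a trended robust prior, array weights, the replicate number as a block, brighter features only (mean above 4.99, the percentile 40 of those tested), all features, 1 feature per gene, ordinary per-feature variances, and leaving out each array in turn. For lists, estimated correlation, fry and the mean of a gene's features were added. The procedure was tested on 20 simulated data sets for the comparison of AA2G with untreated cells over 23521 features, with 200 changed. It recovered 67.2% of changes of 0.5 on the log2 scale, 99.4% of changes of 1 and 100% of changes of 2, and 5.71% of its calls were false. For lists over 22180 genes, it recovered a shift of 0.3 in 20 of 20 simulations and made 0 false calls. All simulations drew genes independently of each other and held no effect shared by replicate number. The shifted list was that of glycolysis, whose estimated correlation in the data was 0.71. These figures therefore do not tell how the tests behave with correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.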

Results

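The transcriptome of R1 mouse embryonic stem cells was measured on 6 arrays, 3 of untreated cells and 3 of cells kept for 3 days with 0.74 mM AA2G, a stable vitamin C derivative. Array medians lay between 5.06 and 5.10 on the log2 scale. Over all features, pairs of arrays within a group correlated at r = 0.9902 to 0.9924 and pairs across groups at r = 0.9886 to 0.9912, correlations taken across features, which are not independent replicates. The first principal component held 34.2% of the variance and separated the AA2G arrays from the untreated arrays. The second held 26.6% and ordered the replicate numbers alike in both groups. The design asks which genes 3 days of AA2G change in embryonic stem cells held in serum and LIF.

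Several genes that are normally used in the germ line were higher in cells kept with AA2G. Zfp951 (Entrez Gene 626391), a zinc finger gene, had the largest fitted rise among the genes past the threshold, from 2.44 ± 0.20 in untreated cells to 5.92 ± 0.35 with AA2G (SD, n = 3 each). Its untreated value cannot be told from background, so its measured fold of 11.1 is uncertain. Sohlh2 (74434), a germ cell transcription factor, rose 5.48-fold from 8.07 ± 0.11 to 10.5 ± 0.03. Dazl (13164), an RNA-binding protein of germ cells, rose 5.17-fold from 7.06 ± 0.24 to 9.43 ± 0.19, and Rec114 (73673), which is needed for meiotic double-strand breaks, rose 5.01-fold from 5.55 ± 0.16 to 7.87 ± 0.08. Falls past the threshold were smaller, and the largest of them was that of the growth factor gene Pdgfc (54635), from 7.92 ± 0.04 to 6.66 ± 0.08.

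In the limma model 179 of 23521 features, standing for 177 genes, passed a Benjamini-Hochberg adjusted p of 0.05. Of these, 143 were higher with AA2G and 36 were lower, so 79.9% of the changes were rises. A change of at least 1.5-fold was reached by 118 of the higher and 22 of the lower features, and a change of at least 2-fold by 61 and 1. The median log2 fold change was 0.89 among the higher features, -0.63 among the lower ones and -0.01 over all features. The higher genes had started from a median untreated level of 5.24 and the lower ones from 7.19, against 5.51 for all features. At an unadjusted p under 0.05 there were 1095 higher and 1189 lower features, where 1176 in all would pass by chance. For 3692 features (15.7%, where chance gives 10%) the 3 AA2G arrays all lay on one side of the 3 untreated arrays, and this held for each of the 179. The number of calls moved with single arrays: it was 98 without untreated replicate 1, 101 without untreated replicate 2, 64 without untreated replicate 3, 89 without AA2G replicate 2 and 88 without AA2G replicate 3. It rose to 277 with a trended robust prior and to 496 with array weights, and fell to 13 with ordinary per-feature variances. The share of rises moved too, to 61.1% with array weights (303 higher and 193 lower), 65.7% with brighter features only (165 and 86) and 90.6% without untreated replicate 3 (58 and 6).

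**Figure D1:**
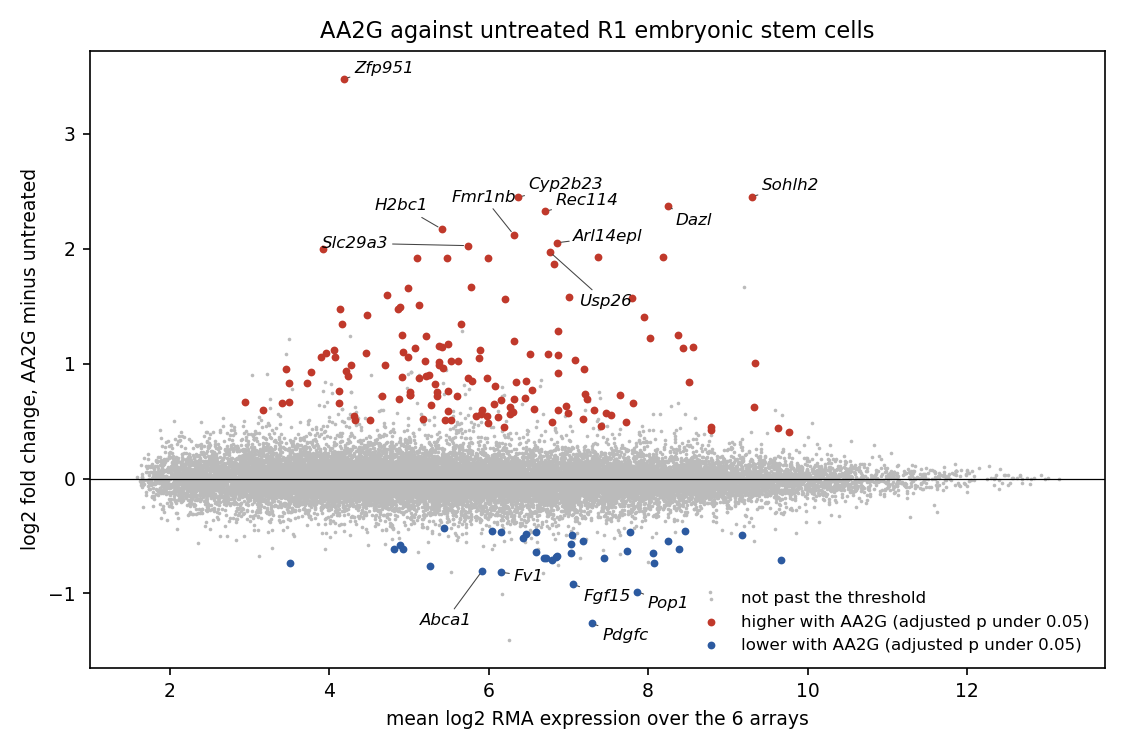
Log2 fold change (AA2G minus untreated, vertical axis) of each of the 23521 features tested against its mean log2 RMA expression over the 6 arrays (horizontal axis); red points were higher and blue points lower at an adjusted p under 0.05. The 61 rises of at least 2-fold reach 3.48 for Zfp951, while the largest fall among the blue points is -1.26 for Pdgfc.

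The other genes among the 10 largest rises were Cyp2b23, H2bc1, Fmr1nb, Arl14epl, Slc29a3 and Usp26. Cyp2b23, a cytochrome P450 gene, rose by 2.45 ± 0.13 on the log2 scale (SE; limma adjusted p = 0.000214). H2bc1, a testis-specific histone H2B gene, rose by 2.17 ± 0.25 (adjusted p = 0.00851), a call that was lost without untreated replicate 3 (adjusted p = 0.0515). Fmr1nb rose by 2.12 ± 0.07 and Usp26, a deubiquitinase gene of the testis, by 1.97 ± 0.12, and both lie on the X chromosome. Arl14epl rose by 2.05 ± 0.16. Slc29a3, a nucleoside transporter gene, rose by 2.03 ± 0.11 at one of its features, while its other feature had a value of 0.01 (adjusted p = 0.973). For the leading genes the adjusted p was 0.00021 for Zfp951, 2.25e-05 for Sohlh2 and Fmr1nb, 0.000284 for Dazl and 6.89e-05 for Rec114.

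Pdgfc fell by 1.26 ± 0.07 (SE; limma adjusted p = 0.000284). The next largest falls were those of Pop1, a subunit gene of RNase P, at -0.98 ± 0.13 (adjusted p = 0.0167), and of Fgf15, a growth factor gene, at -0.92 ± 0.13 (adjusted p = 0.0211). Each of these has a second feature that did not pass, at -0.04 for Pop1 and -0.19 for Fgf15. Fv1, a retroviral restriction gene, was at -0.82 ± 0.10, the cholesterol exporter Abca1 at -0.80 ± 0.09 and the guidance factor Sema3e at -0.76 ± 0.12. Actn3, a muscle α-actinin gene, was at -0.73 ± 0.08, Pml, which forms nuclear bodies, at -0.71 ± 0.09, the long non-coding RNA Platr22 at -0.71 ± 0.08 and the G protein subunit Gnai1 at -0.69 ± 0.08, with adjusted p between 0.00593 and 0.0284 from Fv1 to Gnai1. Of these 10 falls, those of Pdgfc and Actn3 stayed past the threshold with each array left out. Without untreated replicate 3 the adjusted p was 0.0787 for Pop1, 0.0561 for Fgf15, 0.0519 for Abca1, 0.0590 for Sema3e, 0.0787 for Pml, 0.0501 for Platr22 and 0.0561 for Gnai1, and Fv1 was at 0.0627 without AA2G replicate 3. In a fit of all features of the table, Pop1 (0.0726), Fgf15 (0.0807), Sema3e (0.101) and Pml (0.0645) did not pass.

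Of the 29 gene lists, the germline genes moved most. Of 30 measured germline genes, 8 rose, 0 fell and 22 did not pass, and 18 were higher when adjusted over the list alone. The list median was 0.39, and 24 members had a positive value. Besides Sohlh2 and Dazl, Mov10l1, a helicase of the piRNA pathway, rose by 1.57 ± 0.08 (SE; limma adjusted p = 0.000212) and Rpl10l, a ribosomal protein gene of the testis, by 1.87 ± 0.11 (adjusted p = 0.000284). The other 4 risers, named here after their values were seen, were the meiotic chromosome genes Hormad1 (1.92) and Smc1b (1.58) and the piRNA pathway genes Mael (1.14) and Piwil2 (0.73). Other members did not pass, among them Ddx4, the germ cell helicase known as Vasa, at -0.17, Tex101 at -0.14 and Sycp1, of the synaptonemal complex, at 0.24, all 3 likewise picked after their values were seen. Camera gave an adjusted p of 4.54e-20 at the preset correlation, and the adjusted p was 0.157 with an estimated correlation. Fry gave an adjusted p of 0.00259.

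**Figure D2:**
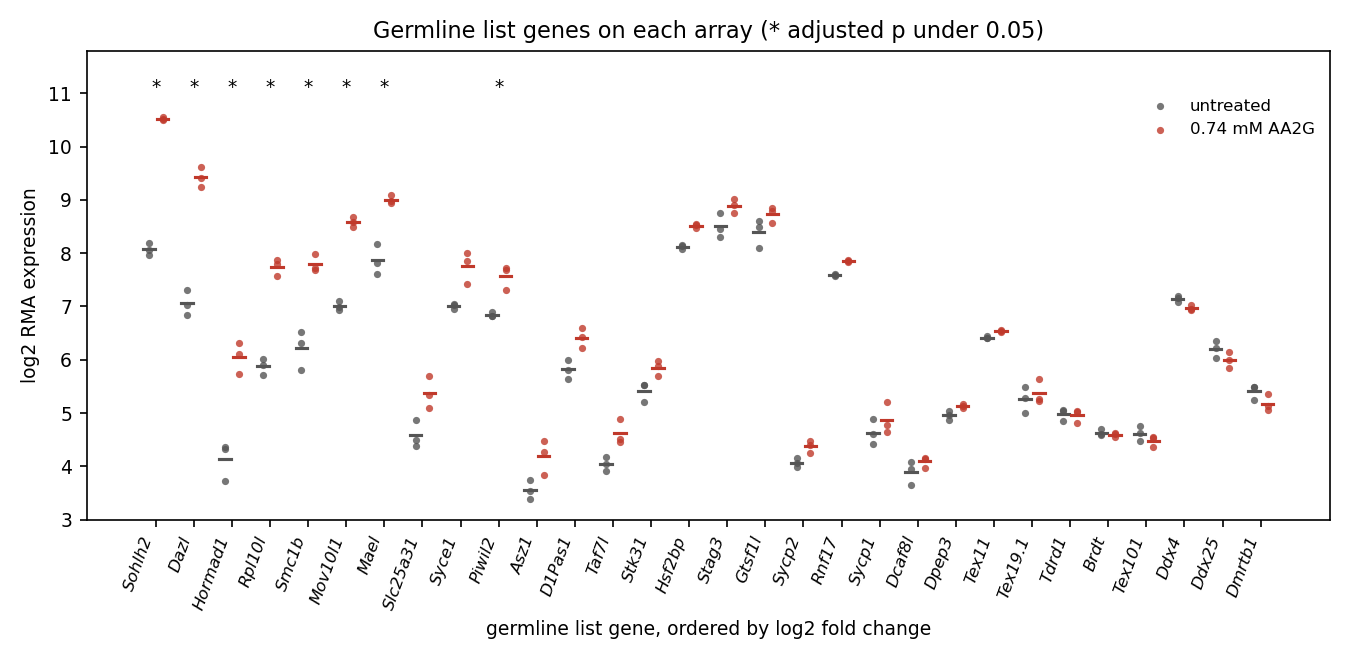
Log2 RMA expression (vertical axis) of the 30 measured germline genes (horizontal axis, ordered by log2 fold change) on each of the 3 untreated arrays (grey) and the 3 arrays with 0.74 mM AA2G (red), with short lines at the group means. Stars mark the 8 genes past an adjusted p of 0.05, from Sohlh2 (2.45) to Piwil2 (0.73).

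Of 107 measured markers of 6 other cell types, limma called 0 higher and 0 lower, and at an unadjusted p under 0.05 there were 3 higher and 9 lower. The primitive endoderm list of 21 measured genes had a median of -0.02, with the basement membrane genes Lama1 at 0.50 ± 0.09 (SE; limma adjusted p = 0.0706) and Sparc at 0.34 ± 0.07 (adjusted p = 0.0925), and these 2 were higher when adjusted over the list alone and passed with the trended robust prior (0.0336 and 0.0345). Of 13 trophoblast genes, 3 were lower when adjusted over the list alone, among them the keratin gene Krt8 at -0.35 ± 0.07 (adjusted p = 0.0894) and Rhox6 at -0.39 ± 0.11. Medians were -0.03 for 17 mesoderm and primitive streak genes (Mixl1 -0.23), 0.00 for 19 cardiac muscle genes (Actn2 0.17), -0.01 for 17 neuroectoderm genes (Sox1 -0.19) and -0.04 for 20 fibroblast feeder genes (Ccn2 -0.28, with its second feature at 0.21), with 0 members of these 4 lists past the threshold over all features or over the list alone. The camera adjusted p of the 6 lists was 0.597 for trophoblast and from 0.826 to 0.981 for the rest.

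Among the pluripotency genes, Nanog was at 11.3 ± 0.03 in untreated cells and 11.2 ± 0.04 with AA2G (SD, n = 3; limma adjusted p = 0.445), and Pou5f1, which encodes Oct4, at 7.64 ± 0.02 and 7.47 ± 0.01 (limma adjusted p = 0.455). Of 21 naive pluripotency genes, 1 rose, Fbxo15, a target gene of Oct4, by 0.63 ± 0.07 (limma adjusted p = 0.00625). Klf4, at -0.31 ± 0.07, did not pass (adjusted p = 0.127), and over the list alone 1 gene was higher and 2 were lower. Of 11 core pluripotency genes 0 passed in limma, 1 was lower at an unadjusted p under 0.05 (Pou5f1), and the median was -0.09. Camera called neither list (adjusted p = 0.727 and 0.384).

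Of 16 genes of the primed epiblast, the later state that follows naive pluripotency, 1 fell (Fgf15), and 5 were lower when adjusted over the list alone. The Nodal pathway genes Lefty1 and Nodal were at -0.72 ± 0.13 (SE; limma adjusted p = 0.0577) and -0.36 ± 0.07 (adjusted p = 0.0823), and Krt18 at -0.43 ± 0.10, with its second feature at 0.12. Lefty1 and Nodal passed with the trended robust prior (0.0232 and 0.0383), with array weights (0.0139 and 0.0174) and with brighter features only (0.0341 and 0.0346), and Lefty1 also without untreated replicate 2 (0.0449). The list was called lower by camera (adjusted p = 0.0259), with a median of -0.05, and the adjusted p was 0.422 with an estimated correlation. That call was also lost without untreated replicate 1 (0.158), without untreated replicate 3 (0.0705), without AA2G replicate 2 (0.134), with the mean of each gene's features (0.0867) and by fry (0.162). The 16 FGF-ERK feedback targets had a median of -0.03, with 0 past the limma threshold, 2 higher and 1 lower at an unadjusted p under 0.05, and Dusp4 at 0.32 ± 0.09 (camera adjusted p = 0.981).

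Transcripts of the enzymes that make, read and remove DNA methylation did not pass. Tet1, which oxidises 5-methylcytosine and uses ascorbate as a cofactor, was at 10.4 ± 0.09 in untreated cells and 10.2 ± 0.04 with AA2G (SD, n = 3; limma adjusted p = 0.354). Tet2 was at -0.17 ± 0.08 (SE) and Tet3 at -0.08 ± 0.08 on the log2 scale. The de novo methyltransferase genes Dnmt3a and Dnmt3b were at -0.14 ± 0.13 and 0.35 ± 0.15, and their cofactor Dnmt3l at 0.31 ± 0.08 (adjusted p = 0.161). The list of 18 genes had a median of -0.07 (camera adjusted p = 0.512), with 1 higher and 2 lower at an unadjusted p under 0.05. The 18 JmjC histone demethylase genes, whose products also use ascorbate, had a median of -0.06 with 15 negative values, 0 limma calls and 1 lower at an unadjusted p under 0.05 (Kdm3a -0.24, Kdm4d 0.20), and a camera adjusted p of 0.173.

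Of 29 imprinted genes, 1 fell, Phlda2, a growth-restricting gene of the placenta, by 0.49 ± 0.07 (SE; limma adjusted p = 0.0279). Over the list alone 7 were lower and 1 was higher. Cdkn1c, a cell cycle inhibitor that lies in the same imprinted domain, was at -0.61 ± 0.11 (adjusted p = 0.0510), Ndn at -0.39 ± 0.08 (adjusted p = 0.0979) and Mkrn3 at -0.35 ± 0.08. The list was called lower by camera (adjusted p = 0.0102, median -0.07), the adjusted p was 0.323 with an estimated correlation, and fry gave 0.00259. The call of Phlda2 was lost in the fit of all features (adjusted p = 0.0902) and without untreated replicate 2 (0.101), untreated replicate 3 (0.166), AA2G replicate 1 (0.0957), AA2G replicate 2 (0.119) and AA2G replicate 3 (0.126). Cdkn1c passed with arrays shifted to 1 median (0.0418), the trended robust prior (0.0294), array weights (0.00990), brighter features only (0.0288), 1 feature per gene (0.0495) and without untreated replicate 1 (0.0437).

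Of 17 p53 target genes, 1 fell, Perp, an apoptosis and desmosome gene, by 0.69 ± 0.08 (SE; limma adjusted p = 0.00851), and 2 were lower over the list alone. The median was -0.22, and 14 of the 17 values were negative, with Eda2r at -0.42 ± 0.14, Ccng1 at -0.33 ± 0.08 and Mdm2, the ubiquitin ligase of p53, at -0.31 ± 0.10. Camera called the list lower (adjusted p = 8.21e-06), and the adjusted p was 0.323 with an estimated correlation and 0.162 by fry. The call of Perp was lost without untreated replicate 3 (adjusted p = 0.0530). Of 25 cell cycle genes 0 passed in limma, 3 were lower at an unadjusted p under 0.05, and 21 were negative, with a median of -0.06. Ccnd2, a G1 cyclin, was at -1.40 ± 0.37 (adjusted p = 0.196, but 0.0185 without untreated replicate 1 and 0.0341 with array weights), and Ccnd1 at -0.38 ± 0.15. Camera called this list lower (adjusted p = 0.0257), with an adjusted p of 0.422 with an estimated correlation, 0.0668 by fry, 0.0577 with brighter features only, 0.0581 without AA2G replicate 1 and 0.0730 without AA2G replicate 3.

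Of 18 genes of the unfolded protein and amino acid stress response 0 passed in limma, 3 were higher and 1 lower at an unadjusted p under 0.05, and 15 were positive with a median of 0.16. Chac1, a glutathione-degrading enzyme induced by this response, was at 0.70 ± 0.23, Herpud1, which acts in endoplasmic reticulum degradation, at 0.57 ± 0.17, Creld2 at 0.23 ± 0.08 and the chaperone gene Dnajb9 at -0.24 ± 0.09. Camera called the list higher (adjusted p = 0.00211), but the adjusted p was 0.422 with an estimated correlation, 0.287 in fry and 0.0531 without untreated replicate 2. The 15 cholesterol synthesis genes had a median of 0.07 with 13 positive values, 0 limma calls and 1 higher at an unadjusted p under 0.05 (Dhcr7 0.24, Hmgcs1 -0.17), and a camera adjusted p of 0.0661. This list passed as higher with quantile normalization repeated (0.0430), with the trended robust prior (0.0214), with brighter features only (0.0395), without untreated replicate 1 (0.0249) and without AA2G replicate 1 (0.0455).

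Other lists tied to vitamin C had 0 genes past the limma threshold over all features or over the list alone, and at an unadjusted p under 0.05 each held at most 1. Among 24 targets of the hypoxia factor HIF, whose hydroxylases use ascorbate, the median was -0.04 (Kdm3a -0.24, Fam162a -0.20), and among 15 glycolysis genes it was -0.05 (Eno2 -0.37). Camera adjusted p was 0.826 and 0.563. Both lists passed as lower without untreated replicate 2 (0.0296 for each) and without AA2G replicate 1 (0.0473 and 0.0463). They turned higher without passing when untreated replicate 1 (0.311 and 0.784) or AA2G replicate 2 (0.335 and 0.954) was left out. Each of these fits leaves a replicate number in a single group. With the replicate number as a block, both lists were lower without passing (0.812 and 0.383). The fits with an array left out therefore do not settle their direction. The glucose transporter gene Slc2a1 was at -0.07 ± 0.10 (SE), with its second feature also at -0.07, and the collagen prolyl hydroxylase gene P4ha1 at -0.12 ± 0.31. Both signs turned positive when some single arrays were left out, although within each replicate number the AA2G array was the lower for both genes. The 19 collagen chain genes had a median of 0.02 (Col1a1 0.17, Col18a1 -0.32) and the 16 collagen-modifying enzymes -0.05 (Loxl3 -0.29, Ppib 0.15), with adjusted p of 0.941 and 0.814. Vitamin C transport and release genes (13, with Glrx at 0.31 and the ascorbate transporter Slc23a1 at -0.18) had a median of 0.00 and an adjusted p of 0.941.

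The remaining lists also held 0 genes called by limma, and from 0 to 3 each at an unadjusted p under 0.05. Medians were 0.02 for 23 NRF2 targets and antioxidant genes (Gclc -0.30, Txnrd1 -0.25), 0.04 for 12 iron and metal genes (Steap3 0.45, Tfrc 0.23), 0.03 for 26 respiratory chain genes (Atp5o 0.21), 0.00 for 22 interferon-stimulated genes (Ifit3 -0.25), 0.02 for 22 ribosomal protein genes (Rpl5 0.20, Rpl11 -0.31) and 0.06 for 20 genes of the 2-cell-like state (Zscan4e 0.24, Zfp352 0.28). Their camera adjusted p was 0.967, 0.597, 0.180, 0.826, 0.727 and 0.597. The median and the mean had opposite signs for trophoblast (0.02 and -0.05), collagen chains, NRF2 targets and vitamin C transport genes, and camera's direction was up against a negative median for cardiac muscle, FGF-ERK and vitamin C transport genes.

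Across the 29 lists camera called 6 at the preset correlation: germline and stress response genes higher, and p53 targets, imprinted, cell cycle and primed epiblast genes lower. With an estimated correlation 0 of the 6 calls held, and camera's unadjusted p was 0.00543 for the germline genes, 0.0225 for imprinted genes and 0.0334 for p53 targets. That setting also uses the 4 residual degrees of freedom, which raises p by itself. The correlation estimated for imprinted genes was -0.012, below the preset 0.01, yet their unadjusted camera p rose from 0.00141. The lost calls therefore do not measure correlation among the genes alone. Other divisions of the 6 arrays into 3 and 3 called as many as 7 lists, and the germline list had an adjusted p under 0.05 in 6 of those 9 divisions, with 0 germline genes called in each. Those divisions hold unequal numbers of AA2G arrays on their sides and so keep part of the AA2G difference. Their calls therefore do not tell what would be called without a treatment.

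**Figure D3:**
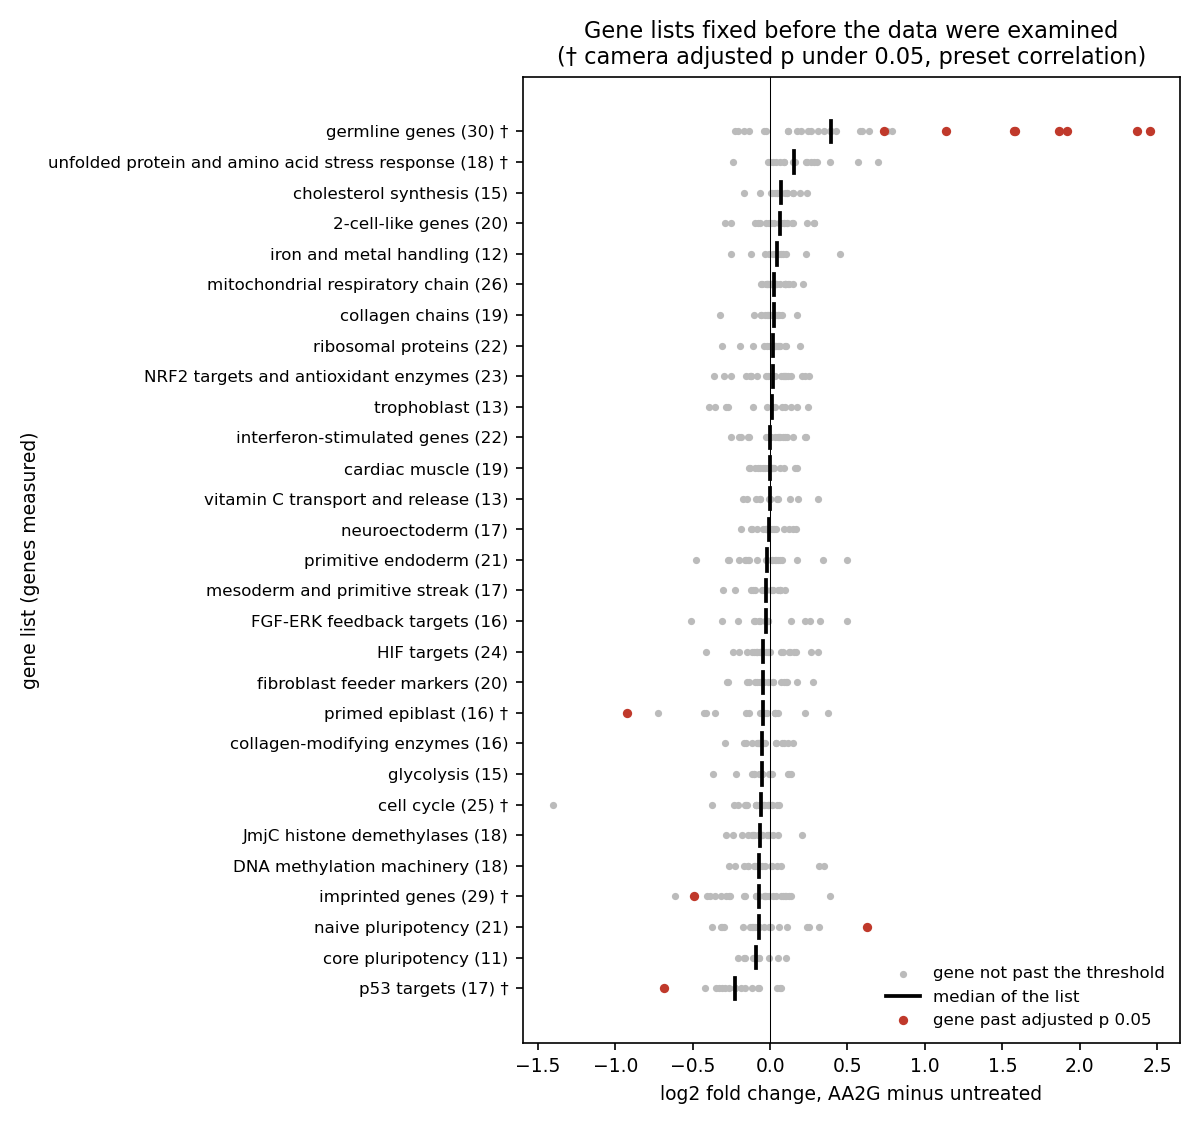
Log2 fold change (AA2G minus untreated, horizontal axis) of each measured member of the 29 gene lists (vertical axis, ordered by median, with the number measured); red points passed an adjusted p of 0.05 and black bars are list medians. The germline median lies at 0.39 and that of the p53 targets at -0.22, while all others lie between -0.09 and 0.16.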

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

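Features outside the named measurement also differed between the groups, which was looked at because those features enter no comparison above. When all 41345 features of the table were fitted together, 46 features with several gene symbols or with none differed between AA2G and untreated arrays at a limma adjusted p under 0.05. Of these, 13 carry several symbols, and all 13 were higher with AA2G. They are not 13 separate signals, since several list the same symbols and some have identical fold changes. Another 33 have no listed symbol, with 25 higher and 8 lower. That fit called 131 features in all, 111 higher and 20 lower. No gene is named from them, and no explanation was tested.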

How the results depend on the processing

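The counts of germline genes under the alternatives and the test of other divisions of the arrays were chosen after the data were seen. Of 348 alternative values of the 25 called named genes, 310 stayed past the threshold, 38 did not and 0 changed sign. In the other direction, 31 values of 12 uncalled named genes passed, 27 of them outside the fits that leave out an array: Klf4, Lefty1, Nodal, Krt18, Lama1, Sparc, Krt8, Cdkn1c, Ndn, Mkrn3, Ccnd2 and Ccng1, mostly with array weights, the trended robust prior or brighter features only. Over all 94 genes named by rule, 3 of 1308 values changed sign, none of them called: Slc2a1 (0.011 without AA2G replicate 2; -0.14 to 0.011 over the arrays left out) and P4ha1 (0.14 without untreated replicate 1 and 0.13 without AA2G replicate 2; -0.40 to 0.14). Repeated quantile normalization gave 180 changed features and a common median 182. A trended robust prior gave 277 changed (79 lower), of which 178 were among the 179. Array weights gave 496 (303 higher, 193 lower, 13 germline genes), with 61.1% of changes higher against 79.9%. The weights were 2.64 for untreated replicate 3 and 2.07 for AA2G replicate 3, and from 0.573 to 0.744 for the other arrays. The weighted fit therefore leans on replicate 3 of each group. Brighter features only gave 86 lower and 65.7% higher, with fewer features tested. All features gave 20 lower, with more features tested, and ended the calls of Pop1, Fgf15, Sema3e, Pml and Phlda2. Ordinary per-feature variances gave 13 changed, 12 of them among the 179. Beyond the number of tests or arrays, the cause was not tested.

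Leaving out 1 array gave 64 (without untreated replicate 3) to 131 (without AA2G replicate 1) changed features, 58 to 115 higher, 6 to 17 lower, 64 to 129 changed at least 1.5-fold, 6 to 9 germline genes and 5 to 8 lists, with fewer samples in each fit. Besides the losses without untreated replicate 3 given above, calls were lost without untreated replicate 1 for Pop1 (adjusted p = 0.0517), Fgf15 (0.0787), Fv1 (0.0574) and Sema3e (0.0714), without untreated replicate 2 for Pop1 (0.0575), Fgf15 (0.0788) and Fv1 (0.0527), without AA2G replicate 1 for Sema3e (0.0884) and Pml (0.0607), without AA2G replicate 2 for Fgf15 (0.0624), Sema3e (0.135) and Pml (0.0580), and without AA2G replicate 3 for Pop1 (0.0814), Fgf15 (0.0933), Sema3e (0.115) and Pml (0.0833). Of the 6 lists, 0 were called with an estimated correlation and 2 by fry, germline and imprinted genes.

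The replicate block gave 155 changed features, 119 of them among the 179, and 9 germline genes. It ended the calls of Sema3e (adjusted p = 0.0832), Phlda2 (0.0654) and the primed epiblast list (0.0800). Deviations of samples that share a number correlated at 0.23, 0.22 and 0.017, and 6 of 6 samples correlated best with their own number. The second principal component (26.6% of the variance) was at 18.1, -13.0 and 2.0 for untreated replicates 1 to 3. With AA2G it was at 9.9, -14.6 and -2.4, the same order. These values are a hint from the data of an effect shared by replicate number. The labels give no pairing, so the main model did not pair the samples and leaves such an effect in its error. The file has no detection calls, so how far dim features lie above background is unknown.

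Of the 10 divisions of the 6 arrays into 3 and 3, 1, the real one, called as many features as the 179 changed, 143 higher, 36 lower or 140 changed at least 1.5-fold, and the highest of the others was 0 for each. For the 6 lists, 3 of the 10 gave as many, and the highest of the others was 7. With 10 divisions no share under 0.05 can be reached. The other divisions also keep part of the AA2G difference, and the rest of it enters the spread within their sides, so none is free of the treatment.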

Other observations

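The genes in this part, its lists of X-linked and neighbouring genes, and the tests of other cell types and of a shift of the whole X chromosome were chosen only after the results were seen. Single genes outside the gene lists that rose are given here as values, with no count of their kind and no test of enrichment. Morc1, a silencer of transposons in male germ cells, rose by 1.93 ± 0.10 on the log2 scale (SE; limma adjusted p = 0.00021). The meiosis genes M1ap (0.95), Terb2 (0.87), Hormad2 (0.72) and Stra8, the retinoic acid target at meiotic entry (0.77), rose too, as did the testis linker histone H1f6 (0.89), the sperm lactate dehydrogenase Ldhc (0.76), the testis proteasome subunit Psma8 (1.08) and the oocyte gene Khdc3 (0.92). Other risers were the water channel Aqp3 (1.22), the receptor Epha4 (1.15), the collagen receptor Ddr2 (1.14) and the plasma protein genes Fetub (1.67) and Cpn1 (1.25). Sfmbt2, an imprinted Polycomb gene, rose by 0.89 ± 0.11 (adjusted p = 0.00961).

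On the Y chromosome, Uba1y (0.64, limma adjusted p = 0.0212) and Kdm5d (0.66, adjusted p = 0.0310) rose, while Uty was at 0.24 (adjusted p = 0.517) and Eif2s3y at -0.16 (adjusted p = 0.758). The risers were dim in untreated cells, Uba1y at 4.95 and Kdm5d at 3.08, against a median of 5.51 over all features. Uty was at 6.54 and Eif2s3y at 8.23. How far the dim values lie above background is unknown.

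The rise of germline genes could come from a technical shift of dim features or from a change in cell types. The germline median lay at percentile 100 of 10000 random lists matched on untreated level, whose central 95% ran from -0.06 to 0.04, which argues against a drift of dim features. Of 107 markers of 6 other cell types 0 were called higher, an exact upper limit of 3.39%, against 26.7% of germline genes (12.3% to 45.9%, where both intervals treat genes as independent). These counts were known when the test was chosen. Over single lists alone, 2 primitive endoderm genes, Lama1 and Sparc, were higher and 3 trophoblast genes were lower. The markers as a set argue against a broad rise of these somatic or extraembryonic cells as the source, but a small share of primitive endoderm cells was not excluded. More cells of a germ cell type cannot be told apart from a rise within stem cells. The median of 10 primordial germ cell markers was -0.012 with 0 called by limma (the highest was Ifitm3 at 0.48). With only 10 markers, the exact upper limit of the share of markers called higher was 30.8%, and no share of cells was estimated. Of the markers, 3 stand in other lists. Another limit is that 8 lie above the median level of untreated cells, where a small share of cells would be hidden. A rise of germline genes in stem cells themselves remains a hypothesis.

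X-linked genes were over-represented among the genes that rose (such as Rhox13 at 1.92, Rhox5 at 1.57 and Nxf3 at 1.47), 24 of 138 with a known chromosome (17.4%) against 4.09% of 21991 genes, an odds ratio of 5.05 (95% interval 3.09 to 7.94; two-sided Fisher's exact p = 1.83e-09, adjusted over chromosomes 4.02e-08). Of the 36 genes that fell, 4 were X-linked (two-sided Fisher's exact p = 0.0581), and whether rises and falls differ in this was not tested. Bright X-linked genes (mean above 4.99) did not rise as a set: 408 of them lay at -0.030 (-0.05 to -0.01, with genes treated as independent) from 12944 bright autosomal ones. This argues against a shift of the whole X chromosome for bright genes only. Dimmer X-linked risers such as Nxf3 and Ct55, at 3.40 and 3.74 in untreated cells, were not part of it. The dimness of X-linked genes does not account for all of the excess. Draws matched on untreated level held a median of 5 X-linked genes and at most 16, under the 24 observed. With the observed set counted as 1 draw, the percentage holding as many was 0.009999%, the smallest the draws can give. With 1 gene per family and chromosome the odds ratio was 3.42 (1.69 to 6.32). A family is here a shared stem of the gene symbol, such as Nxf or Rhox, and not a set of similar sequences. Genes with predicted or accession-like names were left out, so 12096 genes remained, and a family with a riser was counted as a riser. The reduced set therefore does not decide how far near-identical copies account for the excess. That X-linked genes may respond more often to AA2G remains a hypothesis, since it was found and tested on the same arrays, and whether these genes belong to germline families was not tested.

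Of the same 138 genes, 26 had another riser within 5 places on the chromosome, against a median of 12 in random placements. With the observed placement counted among them, 0.29997% of placements gave as many (permutation p = 0.0029997). Neighbours include Zfp981 (1.93), Rex2 (1.00) and Zfp982 (1.08) on chromosome 4, Ahsg (0.80) and Fetub on chromosome 16, and Rhox5 with Rhox2-ps on the X. With 1 gene per family kept by the same rule, which leaves out genes with predicted or accession-like names, 14 of 104 had such a neighbour. There 28.99% of placements gave as many, the observed one included. Chance placement is thus argued against for the full set. Near-identical copies that stand side by side, or probes that read several of them, may account for the excess. The reduced set cannot show this, since neighbours such as Gm15080, Gm15114, Gm15127 and Gm15091 were dropped for their names and not as copies. Shared control of neighbouring genes stays open and was not tested.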
